A study of Homo sapiens with 7 samples.

How the data were processed

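H3K9me3, the histone mark laid down by SETDB1 and other lysine methyltransferases, was profiled by ChIP-seq in THP-1, an established human acute monocytic leukaemia cell line. Per the labels' protocols, cells received a lentiviral guide RNA against SETDB1 (guide 6 or guide 9) or a non-targeting control (NTC), were selected with puromycin, and gave chromatin cut with micrococcal nuclease. The 7 libraries were 2 NTC IP, 1 guide 6 IP, 1 guide 9 IP and 1 input for each of NTC, guide 6 and guide 9. The comparison of conditions set the guide 6 and guide 9 IP libraries (SETDB1 IP, n = 2) against the NTC IP pair (n = 2). The labels do not say whether the libraries came from separate cultures, so p-values measure the spread between these samples, which may be technical. SETDB1 RNA or protein was not analysed here, so the disruption itself was taken from the labels.

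The authors deposited estimated counts per repeat subfamily for all 7 libraries, made with RepEnrich according to the name of the deposited table, a program that shares a read between the subfamilies it maps to. The values were already whole numbers as deposited, so rounding changed none of them. The version of RepEnrich and the repeat annotation are not given in the sources used here. The submitters' processing notes name Bowtie2 2.2.3, Bowtie, MACS2 and the genome build hg19, without saying which aligner served which file. Because reads from related subfamilies are shared, neighbouring subfamilies of a family are not independent measurements.

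Peaks were called with MACS 2.1.0.20150420 on 1 IP library against its own input, per the file headers, as narrow peaks at a q cutoff of 0.05 with 1 tag kept per position. The lists were for NTC replicate 1, guide 6 and guide 9, and replicates were not pooled; no list of NTC replicate 2 was used here. In the deposited peak lists each peak has a position and length in bp, a pileup (the fragment signal at the summit), a -log10 p and a -log10 q, and a fold enrichment, which is the ratio of the summit pileup to the local background, per the file headers. These per-peak values are the peak caller's, as the authors deposited them, and served here only to describe or filter peaks within a list.

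Repeat counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test with TMM factors over the 4 IP libraries, after filterByExpr removed 33 of 1116 subfamilies. Adjusted p-values are Benjamini-Hochberg values over the 1083 subfamilies tested, with a threshold of 0.05. DESeq2 1.42.0 was the second tool. Sets of subfamilies were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with fry and with camera at an estimated correlation beside it. A list said below to pass or to be called did so at the preset correlation only. With fry and with the estimated correlation 0 lists were lower and 0 higher. The 31 sets were the repeat families of the table with at least 10 tested subfamilies and lists matched by name with at least 3. Log2 CPM (counts scaled to library size) used a prior count of 2, and log2 ratios of IP over input a prior count of 0.5. The guides were compared by size alone (at least 2 times apart, with a mean of at least 500 counts), a rule chosen after seeing the data; the test planned for them was dropped, since each guide has 1 library and its spread would have come from the NTC pair. Class shares were compared by an exact two-sided permutation test, which cannot go below p = 0.333 with 2 libraries against 2. The list, region and subfamily choices, the tests and most alternatives were fixed before the data were examined; later additions are named in the closing section.

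The rule for named subfamilies took the largest changes past the threshold, which gave none, and 21 subfamilies fixed in advance, from L1HS to the alpha satellite. Gene lists were not run, since no annotation of hg19 was used here and the gene table at hand belongs to another build; fixed regions in hg19 coordinates took their place. Overlap between peak lists was counted from 1 bp, with 95% exact Clopper-Pearson intervals for shares of peaks, which cover counting error only. Chance overlap came from 20 shifts of a list along its chromosomes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used for peaks.

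The fit was tested on simulated data with 200 of the 1083 subfamilies changed. At the spread of the comparison of SETDB1 IP with NTC IP, it recovered 99.0% of subfamilies changed by 1 on the log2 scale and 100% of those changed by 2, with 7 false calls. At the spread of the NTC pair alone it recovered 97.0% and 100%, with 5 false calls. Every simulated subfamily had the same spread and was drawn independently, and no smaller change was simulated. These shares are therefore not the power for small changes or for subfamilies with a larger spread. In the data SVA_D, with a log2 change of 1.97 ± 0.66 (SE), was not called. The NTC IP pair differed by 79.8 times its degrees of freedom in a chi-square test over subfamilies, far above sampling noise, and was kept as 2 samples. Repeat counts ran from 10721860 to 13723417 per library, which makes counting error small beside the spread between libraries for all but the rarest subfamilies. The alternatives tried were other scalings, no filter, other tests and thresholds, the replicate number as a block, the inputs in an interaction, each IP library left out, and stricter, longer or equal numbers of peaks.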

Results

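H3K9me3 over transposable elements and along the genome was compared between THP-1 cells carrying a guide RNA against SETDB1 and cells carrying a non-targeting control (NTC), 5 days after disruption. SETDB1 is a histone methyltransferase that writes H3K9me3 and keeps many transposable elements silent. The repeat table held 13414886 and 13678883 repeat counts in NTC IP replicates 1 and 2, 12292344 in the guide 6 IP and 12066468 in the guide 9 IP. The inputs held 13723417 (NTC), 10864772 (guide 6) and 10721860 (guide 9). Peak calling had 21244153, 19181285 and 19929692 IP tags for NTC replicate 1, guide 6 and guide 9.

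LINE elements made up a smaller share of the H3K9me3 IP in both SETDB1 libraries than in both NTC libraries, and SINE elements a larger one. The LINE share was 36.4% ± 1.94 (SD, n = 2) in NTC IP and 31.5% ± 0.125 (SD, n = 2) in SETDB1 IP, where the inputs held 31.1% (NTC), 30.6% (guide 6) and 31.1% (guide 9). The SINE share was 23.3% ± 2.19 in NTC IP and 27.2% ± 1.01 in SETDB1 IP, below the 35.5% to 35.9% of the inputs. LTR elements held 22.8% ± 0.626 and 23.8% ± 0.168, and satellites 11.4% ± 0.791 and 10.7% ± 0.0116, against 5.92% to 5.95% of the inputs. The SVA elements, a small hominoid group, held 0.324% and 0.268% of the 2 NTC IP libraries, 0.930% of guide 6 and 0.382% of guide 9. The exact two-sided permutation test gave p = 0.333 for each of these shares, the smallest value that 2 libraries against 2 allow.

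**Figure D1:**
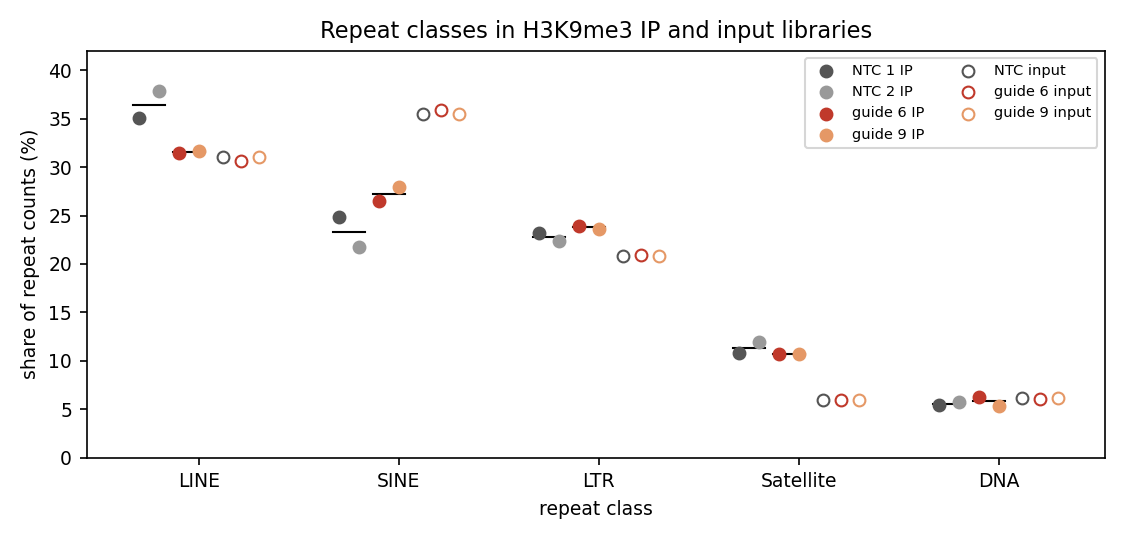
Share of repeat counts (%, y axis) of 5 repeat classes (x axis) in each IP library (filled points, black lines are the means of 2 libraries) and each input (open points). The LINE share lies at 35.1% and 37.8% in NTC IP and at 31.4% and 31.6% in the guide libraries, close to the inputs.

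LINE-1 (L1), the autonomous retrotransposon of the human genome, fell as a family relative to the other repeats in the SETDB1 IP. Over 131 subfamilies the median log2 change was -0.28 (-0.25 with guide 6 and -0.29 with guide 9), and 113 lay below both NTC libraries with both guides, against 7 above. The median was -0.33 in the old mammalian L1 list (92 subfamilies, of which 71 were lower and 2 higher when adjusted over the list alone), -0.22 in the older primate L1 list (17 subfamilies, 10 lower when adjusted over the list alone) and -0.20 in the young L1 list (9 subfamilies, 8 lower when adjusted over the list alone). The lists were not tested against each other. Without NTC replicate 2 the median was -0.20 for the L1 family, -0.23 for mammalian, -0.16 for older primate and -0.19 for young L1. Among the young elements the log2 change was -0.24 ± 0.06 (SE) for L1HS, the human-specific subfamily, -0.22 ± 0.06 for L1PA2, -0.20 ± 0.06 for L1PA3, -0.18 ± 0.06 for L1PA4 and -0.13 ± 0.07 for L1PA7, each below both NTC libraries with both guides. Their edgeR adjusted p-values ran from 0.0596 (L1HS) to 0.176 (L1PA7), above the threshold. With camera at the preset correlation of 0.01 the adjusted p was 1.23e-17 for the L1 family, 3.64e-16 for mammalian L1, 0.000663 for older primate L1 and 0.00245 for young L1. The correlation estimated from the data was 0.658, 0.722, 0.728 and 0.97 for these lists, far above the preset one. With it the camera adjusted p was 0.782 for each, so these calls rest on the preset value. With fry the adjusted p ran from 0.277 to 0.321. The young L1 call was lost without guide 6 (adjusted p = 0.133) or guide 9 (adjusted p = 0.188) and the older primate call without guide 9 (adjusted p = 0.0668), and NTC replicate 1 itself lay below replicate 2 by a median log2 difference of -0.16 over the L1 family, -0.19 over mammalian L1, -0.10 over older primate L1 and -0.03 over young L1.

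Alu elements, the primate SINEs that depend on L1 to move, rose as a family relative to the other repeats. Counts were scaled within each library, so a rise of Alu cannot be told from a fall of other repeats. A change in the total amount of H3K9me3 cannot be seen either. Their median log2 change was 0.35 over 41 subfamilies, with 39 above both NTC libraries with both guides, and the 33 AluS and AluY subfamilies had a median of 0.38. All 33 were higher at an unadjusted edgeR p under 0.05, so adjusting over the list alone kept all 33 and adds nothing to it. AluY, with a log2 change of 0.26 ± 0.11 (SE, edgeR adjusted p = 0.119), and AluSx, with 0.29 ± 0.10 (edgeR adjusted p = 0.0995), are among them and did not pass when adjusted over all 1083 subfamilies. All 6 SVA subfamilies were higher at an unadjusted edgeR p under 0.05, and so also when adjusted over the list alone, with medians of 1.01 with guide 6 and 0.38 with guide 9. The adjusted p with camera was 4.94e-12 for the Alu family, 7.48e-12 for AluS and AluY and 0.00608 for SVA, and adjusted p = 0.782 with an estimated correlation for each. The estimated correlations were 0.968, 0.986 and 0.607, far above the preset 0.01. NTC replicate 1 lay above replicate 2 by a median of 0.29 over the Alu family and 0.28 over SVA, and Alu stayed below its input level in all 4 IP libraries (medians from -0.83 to -0.32). Without NTC replicate 2 the median was 0.20 for the Alu family, 0.23 for AluS and AluY and 0.61 for SVA, and the log2 changes of AluY and AluSx were 0.13 and 0.16. With total tags as library size, which also leaves out NTC replicate 2 because its tag total was not at hand, these were 0.16, 0.19, 0.58, 0.09 and 0.12.

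Endogenous retroviruses and satellites went both ways. The ERVL family passed upward as a set (median 0.14, 121 subfamilies, 88 above both NTC libraries with both guides, camera adjusted p = 2.03e-11), as did Gypsy (0.15, 15 subfamilies, adjusted p = 0.00267), the list named HERV-H (0.19, 21 subfamilies, adjusted p = 0.0366) and MST (0.10, 15 subfamilies, adjusted p = 0.0376), each with adjusted p = 0.782 with an estimated correlation. When adjusted over the list alone, edgeR called 0 subfamilies of ERVL, Gypsy and MST (49, 6 and 3 higher and 0 lower at an unadjusted p of 0.05), and 4 higher and 2 lower in HERV-H. The ERVK family had a median of -0.07 over 42 subfamilies, with 19 below and 5 above both NTC libraries with both guides, and did not pass (camera adjusted p = 0.123). Its median was -0.12 without NTC replicate 2 and -0.16 with total tags as library size. The name pattern of the HERV-H list also took in other LTRs whose names begin with LTR7, such as LTR70, and its members were 18 ERV1 and 3 ERVL subfamilies. The list named centromeric satellites passed upward as well (0.40, 18 subfamilies, 11 higher and 3 lower when adjusted over the list alone, camera adjusted p = 0.0376, and adjusted p = 0.782 with an estimated correlation). Only 6 of its members are annotated as centromeric (9 Satellite, 2 telomeric and 1 acrocentric), and its most abundant members, ALR_Alpha and HSATII, had log2 changes of -0.07 ± 0.10 and -0.17 ± 0.09. Gypsy was lost without guide 9 (adjusted p = 0.532), MST without NTC replicate 2 (0.158) or guide 6 (0.541), the satellites without NTC replicate 1 (0.0801) or guide 9 (0.119), and HERV-H without NTC replicate 2 (0.151), guide 6 (0.145) or guide 9 (0.532), each given as an adjusted p. Log2 changes of single elements were 0.26 ± 0.07 for HERVH-int, 0.33 ± 0.09 for LTR7, 0.26 ± 0.09 for LTR12C, 0.09 ± 0.07 for HERV9-int, -0.14 ± 0.07 for HERVK-int, -0.14 ± 0.07 for THE1B and 0.02 ± 0.08 for MER41B, none past the edgeR threshold. Without NTC replicate 2 LTR12C was at 0.16 and HERV9-int at 0.04, and THE1B was at -0.08 without guide 9. With total tags as library size, again without NTC replicate 2, LTR12C was at 0.12, HERV9-int at 0.00231, HERVH-int at 0.16 and LTR7 at 0.20, and the medians were 0.09 for ERVL, 0.11 for HERV-H, 0.05 for MST and 0.26 for the satellites. Without NTC replicate 2 alone HERVH-int was at 0.19 and LTR7 at 0.24, and these medians were 0.13, 0.15, 0.09 and 0.30.

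Of the families of old DNA transposons, 2 were called lower. The median was -0.12 over 72 hAT-Charlie subfamilies (camera adjusted p = 0.00835) and -0.16 over 59 TcMar-Tigger subfamilies (camera adjusted p = 9.11e-05), with adjusted p = 0.782 with an estimated correlation for both and 0 subfamilies of either called when adjusted over the list alone (edgeR had 22 and 21 lower and 1 and 2 higher at an unadjusted p of 0.05). Without NTC replicate 2 the medians were -0.06 and -0.10. The hAT-Charlie call was lost without NTC replicate 2 or guide 6, and the TcMar-Tigger call without guide 9. In that last fit the direction of the camera test turned upward, although the TcMar-Tigger median with guide 6 against the NTC mean was -0.12. The TcMar-Tigger share of repeat counts was 1.74% and 1.89% in NTC, 2.53% with guide 6 and 1.51% with guide 9, so some abundant members stood higher in the guide 6 library while 43 of its 59 subfamilies lay below both NTC libraries with both guides. The other 17 sets did not pass, with adjusted p-values from 0.0765 to 0.974. Among them the medians were 0.21 for AluJ, 0.07 for HERV9 with LTR12, -0.0023 for the list named HERV-K, -0.02 for MER41, 0.05 for THE1, 0.05 for MLT1, -0.01 for the internal regions of endogenous retroviruses and 0.07 for L2 with MIR, and those of HERV-K and the internal regions turned sign with DESeq2 size factors and that of THE1 without NTC replicate 2 (-0.00124). Without NTC replicate 2 the AluJ median was 0.107 and that of MER41 was -0.095. The direction of the camera test differed from the sign of the median for HERV-K (up), THE1 (down), the Satellite family (up, median -0.11) and tRNA (down, median 0.02, mean -0.06), with adjusted p-values from 0.936 to 0.974. The tRNA median turned to -0.0031 with no TMM factors, -0.10 with total tags and -0.06 without NTC replicate 2. The Satellite family median was -0.07 without NTC replicate 2. The HERV-K list, matched by name, held 42 ERVK subfamilies and 68 of other families. The ancient elements L2a and MIR had log2 changes of 0.07 ± 0.07 (edgeR adjusted p = 0.506) and -0.03 ± 0.07 (edgeR adjusted p = 0.741) and did not pass.

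**Figure D2:**
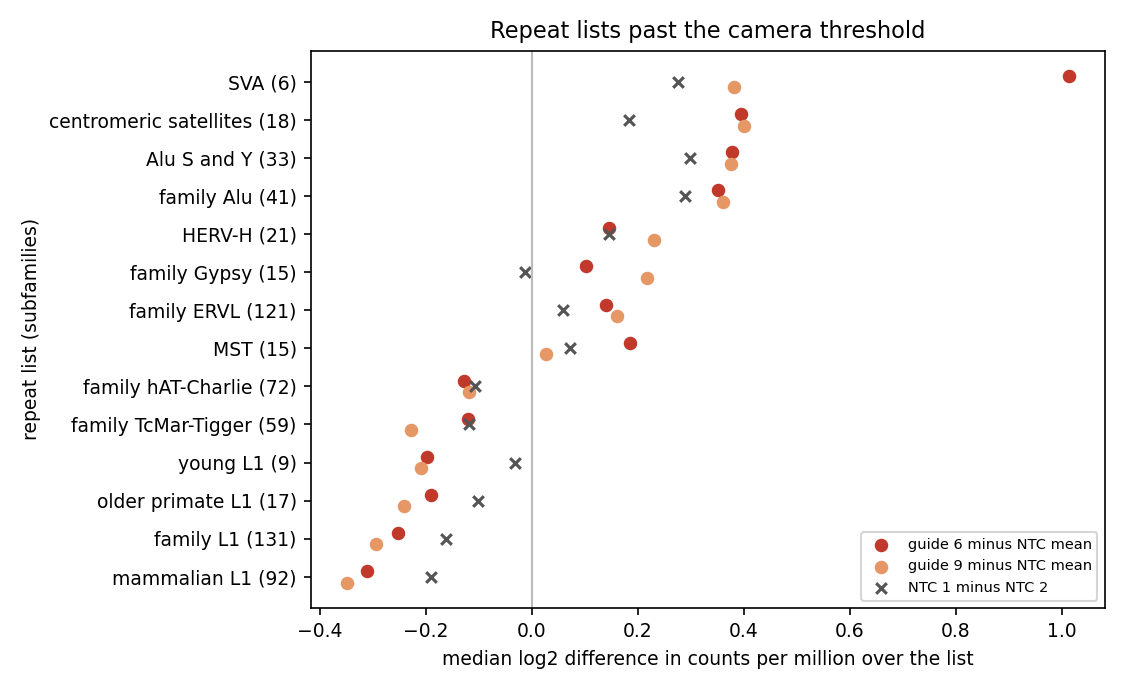
Median log2 difference in CPM (x axis) over the subfamilies of each of the 14 repeat lists past the camera threshold (y axis, number of subfamilies in brackets), for guide 6 and guide 9 against the NTC mean (points) and for NTC replicate 1 minus replicate 2 (crosses). SVA shows 1.01 with guide 6 and 0.38 with guide 9, and the L1 family -0.25 and -0.29.

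Subfamily by subfamily, 417 of 1083 had both guides below both NTC libraries and 366 had both above, where chance gives 33.3% over both directions. The edgeR quasi-likelihood test called 0 subfamilies lower and 0 higher at an adjusted p of 0.05, with the lowest adjusted p, 0.0519, shared by 104 subfamilies. At an unadjusted p of 0.05 it had 235 lower and 189 higher, where 54.2 would be expected by chance, and DESeq2 called 123 lower and 140 higher. Related subfamilies share reads and are not independent. The excess over 33.3% and over 54.2 is therefore not a test of its own, since 1 difference between libraries can move many subfamilies together. By class, 101 of 157 LINE subfamilies were lower and 4 higher at the unadjusted threshold, 35 of 49 SINE subfamilies were higher and 0 lower, and LTR subfamilies were divided between 67 lower and 113 higher of 571. Chosen after their values were seen, the subfamilies with the lowest p were LTR70 (log2 change -0.60 ± 0.07), the satellite D20S16 (0.84 ± 0.10) and the satellite LSAU (0.80 ± 0.11). Without NTC replicate 1 the count was 208 lower and 148 higher, without guide 6 it was 65 and 63, without guide 9 it was 10 and 56, and without NTC replicate 2 it was 0 and 0.

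Against the matched inputs, satellites were the class with the strongest H3K9me3 signal of the 4 abundant repeat classes. Their share was 1.83 and 2.01 times the input in the NTC libraries, 1.80 times with guide 6 and 1.80 times with guide 9. LINE elements were 1.13 and 1.22 times the input in NTC and 1.03 and 1.02 times with guides 6 and 9, and LTR elements 1.11, 1.07, 1.14 and 1.14 times. On the log2 scale L1HS was at 0.66 and 0.70 over input in the NTC libraries, 0.43 with guide 6 and 0.43 with guide 9. The number of subfamilies at least 2 times above input was 12 in both NTC libraries and 9 in both guide libraries, of which 6 were shared, a count chosen after seeing the data. In the edgeR interaction of IP and input with condition over all 7 libraries, 0 subfamilies passed, with 141 lower and 105 higher at an unadjusted p of 0.05; DESeq2 was not run on this interaction.

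The libraries of the 2 guides differed in a distinct group of repeats. Each guide has 1 IP library, so this difference has no replicate check, no test was run, and guide and library cannot be separated here. Among 888 subfamilies with a mean of at least 500 counts, 13 were at least 2 times higher with guide 6 than with guide 9 and 0 lower, while the NTC pair had 0 that far apart. They were 5 TcMar-Tigger DNA transposons, 3 SVA, 2 ERVK, 2 ERVL-MaLR and 1 ERV1 subfamily. Chosen after their values were seen, Tigger3d stood at 1270 CPM with guide 6, 72.0 with guide 9 and 102 in the NTC mean, a log2 difference between guides of 4.14. Tigger4 differed by 2.81, MER65B by 2.64, Tigger3b by 1.88, MER6 by 1.58 and Tigger3 by 1.22. Of the subfamilies fixed in advance, SVA_D differed by 2.34, SVA_A by 1.46 and LTR5_Hs, the youngest HERV-K LTR, by 1.12, while SVA_F lay at 0.33 and 0.39 above NTC with guides 6 and 9 (0.23 for both together without NTC replicate 2). The log2 change in the mean of both guides was 1.97 ± 0.66 for SVA_D, 1.29 ± 0.42 for SVA_A, 0.36 ± 0.10 for SVA_F and 0.70 ± 0.32 for LTR5_Hs, none past the edgeR threshold, and these means rest on guide 6 for all but SVA_F: without it SVA_D was at 0.37, SVA_A at 0.38 and LTR5_Hs at 0.04.

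**Figure D3:**
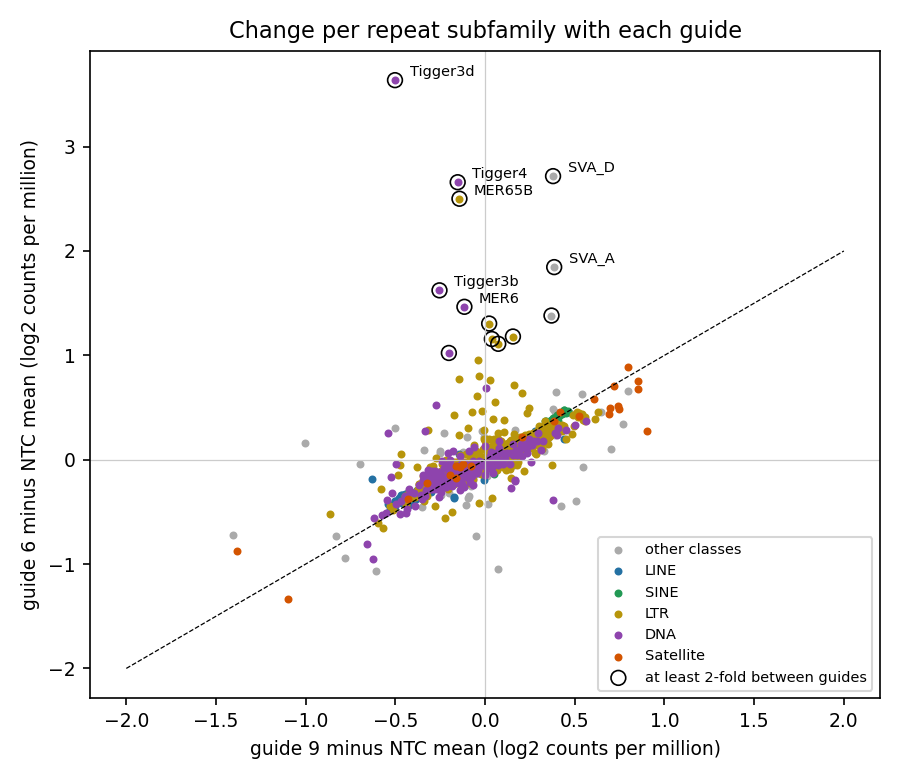
Log2 change in CPM against the NTC mean with guide 9 (x axis) and guide 6 (y axis) for 1083 repeat subfamilies, coloured by class; black rings mark the 13 subfamilies with a mean of at least 500 counts that were at least 2 times apart between guides and the dashed line marks equal change. Tigger3d lies at 3.64 with guide 6 and -0.50 with guide 9, and SVA_D at 2.72 and 0.38.

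Across all subfamilies the changes with the 2 guides were correlated. Pearson's r of the 2 log2 changes was 0.602 over 1083 subfamilies, which are not independent replicates, and 86.9% had the same sign. Both changes share the NTC libraries: simulated unchanged guides gave a mean r of 0.323 and a highest of 0.438 in 100 draws, and the same sign in 60.5% on average and 66.4% at most. The covariance was 0.0549 against 0.00809 simulated, a difference of 0.0468. With separate controls r was 0.434 (guide 6 against NTC replicate 1, guide 9 against NTC replicate 2) and 0.551 in the other arrangement, with covariances of 0.0444 and 0.0485. A difference between libraries that moves related subfamilies together in both guide libraries could also lift r above the simulated draws. The draws cannot tell it from an effect of the guides.

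The peak lists of the 2 guides moved in opposite directions from NTC. There were 39543 H3K9me3 peaks in NTC replicate 1, covering 7.997 Mb, 59856 with guide 6, covering 12.3 Mb, and 14618 with guide 9, covering 2.93 Mb. The ratio to NTC was 1.51 for guide 6 and 0.370 for guide 9 in number, and 1.53 and 0.367 in covered length. Median peak widths were 172, 178 and 176 bp, and the median fold enrichment was 4.57, 4.58 and 5.09. With a fold of at least 4 and a q of at most 1e-05 there remained 5990, 8022 and 2307 peaks, and among peaks of at least 500 bp 629, 695 and 147. The covered length with guide 6 was 1.00 times that of NTC among peaks of at least 500 bp and 1.03 times in equal numbers of top peaks, and with guide 9 it was 0.222 and 0.882 times. Each list came from 1 IP library, so these numbers have no replicate check and no test was run.

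**Figure D4:**
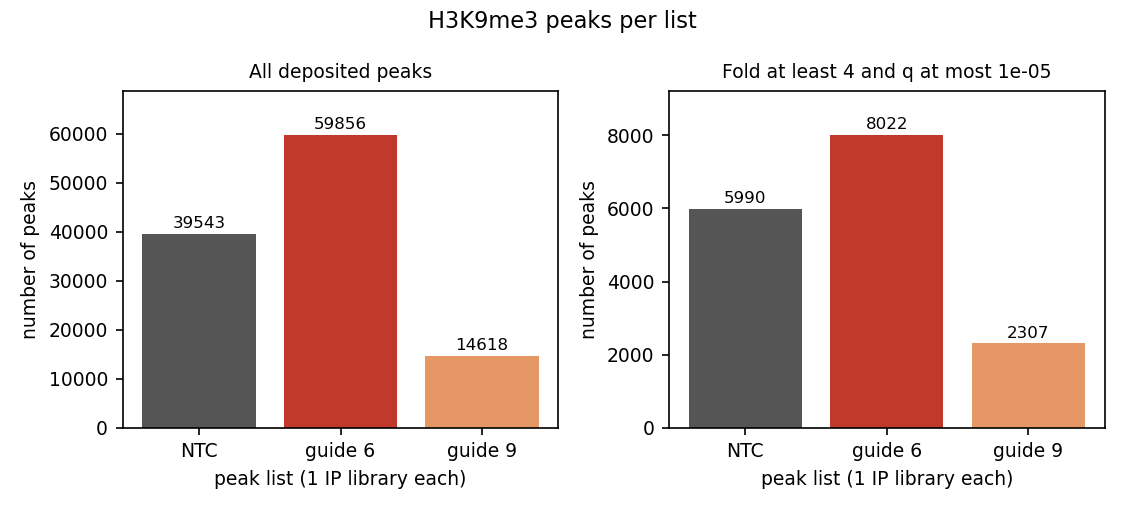
Number of H3K9me3 peaks (y axis, from 0) in the lists of NTC replicate 1, guide 6 and guide 9 (x axis, 1 IP library each), for all deposited peaks on the left and for peaks with a fold of at least 4 and a q of at most 1e-05 on the right. Guide 6 has the most peaks in both panels (59856 and 8022) and guide 9 the fewest (14618 and 2307).

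Most NTC peaks were overlapped by no listed peak of either guide. Of the 39543 NTC peaks, 22.4% (95% interval 21.988 to 22.813) were overlapped by a guide 6 peak and 7.25% (6.997 to 7.510) by a guide 9 peak, where shifted lists gave 1.09% and 0.302%. Both guides overlapped 1504 of them (3.80%) and neither overlapped 29323 (74.2%). Of the guide 9 peaks, 19.8% were overlapped by NTC and 29.6% by guide 6. These contrasts follow the lengths of the lists. In equal numbers of top peaks, 11.1% (10.6 to 11.6) of NTC peaks were overlapped by guide 6 and 10.1% (9.59 to 10.6) by guide 9, and 10.7% (10.2 to 11.2) of guide 9 peaks by NTC and 11.2% (10.7 to 11.8) by guide 6. Among stricter peaks, whose lists also differ in length, the shares of NTC peaks overlapped were 8.78% and 3.14%. No second NTC list was used, so the overlap of NTC replicates, against which these shares would be read, is not known here. The median pileup was 10.0 in the NTC and guide 6 lists and 11.7 in that of guide 9. With signals this small, a peak missing from a list is not shown to have lost the mark.

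Clusters of zinc finger genes on chromosome 19, which carry H3K9me3 in many cell types, took a smaller share of the peaks with the guides at 2 of 3 sites. The lists differ in length, so a share can fall where the number of peaks does not. The cluster at 52 to 54 Mb (hg19) held 200 NTC peaks, 0.506% of the list (95% interval 0.438 to 0.581), 129 peaks or 0.216% (0.180 to 0.256) with guide 6, and 20 peaks or 0.137% (0.0836 to 0.211) with guide 9. At 56 to 59 Mb the shares were 1.02% (0.925 to 1.13), 0.660% (0.597 to 0.728) and 0.588% (0.471 to 0.726), with 404, 395 and 86 peaks, so guide 6 had nearly as many peaks there as NTC. In lists cut to the same 14618 top peaks, the first site held 70, 29 and 20 peaks (0.479%, 0.198% and 0.137%) and the second 170, 93 and 86 (1.16%, 0.636% and 0.588%), with intervals of both guides below that of NTC. Among stricter peaks the first site held 29, 13 and 4 peaks, and the interval of guide 9 (0.0473% to 0.443%) overlapped that of NTC (0.325% to 0.695%). At 20 to 24 Mb the shares were 0.298%, 0.259% and 0.103%, with 118, 155 and 15 peaks: guide 6 had more peaks than NTC there, and the intervals of its share and that of NTC overlapped. Shares in the protocadherin cluster (chromosome 5, 140 to 141 Mb) were 0.0253%, 0.0351% and 0.0205%. In the olfactory receptor clusters they were 0.119%, 0.164% and 0.123% (chromosome 11, 4 to 6 Mb) and 0.0910%, 0.107% and 0.0958% (55 to 57 Mb), with overlapping intervals throughout. The HOXA cluster (chromosome 7, 27 to 28 Mb) and the major histocompatibility complex (chromosome 6, 29 to 33 Mb) held no listed peak with NTC or either guide, and the histone cluster (chromosome 6, 26 to 28 Mb) held 1, in NTC.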

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

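Of the tests below, those of the guide 6 input, of piled reads, of sequencing depth and of weak peaks were chosen, or given their list of subfamilies, after the result was seen.

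In 6 repeat subfamilies guide 6 lay above and guide 9 below both NTC IP libraries. The log2 differences between guides were 4.14 for Tigger3d, 2.81 for Tigger4, 2.64 for MER65B, 1.88 for Tigger3b, 1.58 for MER6 and 1.22 for Tigger3, and were not tested. They came mostly from guide 6, with log2 changes against NTC from 1.02 (Tigger3) to 3.64 (Tigger3d). With guide 9 the changes ran from -0.50 (Tigger3d) to -0.12 (MER6). MER65B was at -0.14 with guide 9, where NTC 1 minus NTC 2 was itself -0.15. The 6 subfamilies belong to 13 at least 2 times higher with guide 6 than with guide 9, with median log2 ratios to NTC IP of 1.47 for guide 6 and 0.02 for guide 9. More copies of these repeats in the guide 6 cells, or DNA from another source in the chromatin, would raise the guide 6 input too, but the median log2 ratio of guide 6 input to NTC input over the 13 was 0.0168 (from -0.08 to 0.08), which argues against it. Reads piled on a few positions stay open: the 171444 extra reads are 0.894% of the guide 6 tags, and redundant tags were 10.21% with guide 6 and 10.25% with guide 9, but reads of a repeat may have been placed at random over its copies, and how they were placed is not given in the sources used here. A difference between the guides themselves stays open and was not tested, since each guide has 1 library.

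The peak number was 1.51 times that of NTC with guide 6 and 0.370 times with guide 9, and the covered length 1.53 and 0.367 times, in opposite directions with 1 library per list; the difference was not tested. The number of IP tags alone does not account for it, because guide 6 had the most peaks and the fewest IP tags kept (17223627, against 17887667 with guide 9 and 19117472 in NTC replicate 1). Input tags kept were 17718794, 17468002 and 22206778 in the same order, and only guide 9 had more IP than input tags. The depth of the IP relative to its input was not tested and stays open. Weak peaks near the threshold stay open. The stricter threshold left ratios of 1.34 and 0.385, and among peaks of at least 500 bp the ratios were 1.10 and 0.234. Each q was computed within its own list, so the same cutoff need not mean the same signal in each list, and this test cannot decide. The strength of the IP may differ: the SD of log2 IP over input across subfamilies was 0.432 with guide 6, 0.371 in NTC replicate 1 and 0.346 with guide 9, in the order of the peak numbers. It cannot be told apart from the first pattern, since without the 13 subfamilies the SD with guide 6 was 0.371, beside 0.373 in NTC replicate 1, and the satellite share was 1.80 times its input with both guides.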

How the results depend on the processing

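The crossed pairing, the guide factor of 3 levels, the size rule between guides, the count above input in both NTC libraries, the simulated share of equal signs and the list medians without NTC replicate 2 were chosen after seeing the data. The count of subfamilies lower and higher in SETDB1 IP, 0 and 0 with edgeR (235 and 189 at an unadjusted p of 0.05), became 123 and 140 with DESeq2, 112 and 118 with the guide factor of 3 levels, 199 and 157 at an adjusted p of 0.1, and from 0 to 208 and from 0 to 148 without 1 library in turn; it stayed 0 and 0 with DESeq2 size factors, no TMM factors, no filter and the inputs in an interaction, and with total tags, a fit that also lacks NTC replicate 2, for which no tag total was at hand. The lowest edgeR adjusted p of 0.0519, shared by 104 subfamilies, lies just above the threshold, while the lowest adjusted p of the DESeq2 Wald test was 1.33e-09. With the replicate number as a replicate block the counts were 120 and 128. The numbers do not pair the samples by any label, and NTC 1 minus NTC 2 correlated with guide 6 minus guide 9 at -0.08 across subfamilies (-0.256 by rank); the crossed pairing gave 172 and 156. The 6 lower and 8 higher lists became 0 and 0 with fry and 0 and 0 with camera at an estimated correlation, 5 and 6 with the replicate block, 6 and 9 crossed, and ranged from 3 to 7 and from 5 to 9 without 1 library in turn; 6 calls held without any single library. Calls gained without NTC replicate 1 were AluJ (adjusted p = 0.0320, higher), LTR12 with HERV9 (0.0458, higher) and CR1 (0.0320, lower), by camera in limma. The r between guides moved from 0.602 to 0.434 with separate controls. The 13 subfamilies at least 2 times higher with guide 6 were 13 by DESeq2 fold changes and 12 with no TMM factors; the DESeq2 test between guides was planned and is not reported, as each guide has 1 library. Without 1 library in turn, the differences in class shares in percentage points ran from -6.27 to -3.53 for LINE (-4.90), from 2.37 to 5.47 for SINE (3.92), from 0.575 to 1.46 for LTR (1.02), from -1.23 to -0.114 for satellites (-0.673), from 0.0854 to 0.634 for SVA (0.360) and from -0.202 to 0.652 for DNA transposons (0.225), which turned sign without guide 6. Of 21 named subfamilies, 19 kept their direction under all 13 alternatives and 13 passed the threshold under at least 1. MER41B (0.02) turned to -0.0343 with total tags (3 libraries), -0.00364 with the inputs and -0.0636 without guide 9 (from -0.0636 to 0.0996 without 1 library in turn), and ALR_Alpha (-0.07) to 0.027 without NTC replicate 2 (from -0.171 to 0.027); both lie near 0 beside their standard errors. Relative to NTC, guide 6 had 1.339 times the number and 1.375 times the length of stricter peaks, 1.105 and 1.004 times those of at least 500 bp, and 1.027 times the length in equal numbers of top peaks. For guide 9 these were 0.385 and 0.358, 0.234 and 0.222, and 0.882. The NTC peaks overlapped by guides 6 and 9 were 16.1% and 4.72% where 50% of the peak had to be covered, 8.78% and 3.14% among stricter peaks, and 11.1% and 10.1% among equal numbers of top peaks, which removes the difference in list length; the other 12 overlap values also moved. For the shares in fixed regions, 38 values stayed within their intervals and 16 moved. Some of the values that stayed could not move. The equal lists hold the whole guide 9 list, and the HOXA and major histocompatibility regions held no peak in any list. Except where a setting changes the number of samples or peaks itself, the cause was not tested. Gene lists and gene bodies with 5 kb on each side were not run, nor was leaving out a library between guides, since each guide has 1; where a condition was left with 1 library, it was assumed to vary like the other condition. Small numbers of peaks leave wide intervals in the regions, as in the protocadherin cluster, where guide 9 had 3.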

Other observations

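The scan of 1 Mb windows and the test of added background were chosen after the results were seen.

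Scanned in 2278 windows of 1 Mb (hg19), 8 held a smaller and 4 a larger share of the peaks with both guides than in NTC, by 95% intervals that did not overlap and were not adjusted for the number of windows. The intervals cover counting error only, with 1 library per list. The window with the largest loss of peak length on a main chromosome was chromosome 8, 86 to 87 Mb, where 129 NTC peaks covering 36300 bp stood against 11 peaks (2368 bp) with guide 6 and 1 peak (197 bp) with guide 9. Of the other 7, 5 lay on chromosome 19, at 12 to 13, 24 to 25, 52 to 53, 53 to 54 and 57 to 58 Mb, the last 3 of them within the zinc finger clusters of the report. At 53 to 54 Mb there were 102 NTC peaks (0.258% of the list), 66 with guide 6 (0.110%) and 7 with guide 9 (0.0479%). At 57 to 58 Mb guide 6 had 190 peaks covering 41081 bp against 198 covering 41099 bp in NTC, so its smaller share there goes with a longer list. In equal numbers of top peaks, the cluster around it at 56 to 59 Mb still held 93 peaks with guide 6 against 170 in NTC. The window itself was not counted in equal lists. The remaining windows were chromosome 7, 61 to 62 Mb, and the unlocalized contig 9_gl000199_random, which went from 157 NTC peaks to 73 and 4. The 4 windows with larger shares were chromosome 1, 34 to 35 Mb, chromosome 10, 119 to 120 and 130 to 131 Mb, and chromosome 17, 31 to 32 Mb, where the share was 0.205% in NTC, 0.364% with guide 6 and 0.458% with guide 9. The larger shares with guide 9 partly reflect its shorter list: the number of peaks was lower than in NTC at 3 of the 4 windows (67 against 81 on chromosome 17, 64 against 104 at 130 to 131 Mb of chromosome 10, and 56 against 86 on chromosome 1). With guide 6 the number was higher at all 4. The genes in these windows were not analysed here.

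Peaks were unevenly spread over the chromosomes in NTC, from 6.17 per Mb on chromosome 4 to 32.9 per Mb on chromosome 19 among the autosomes, counted up to the last peak. Chromosome X had 0.322 per Mb, with 49 peaks in NTC, 96 with guide 6 and 4 with guide 9.

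The lower L1 share in the SETDB1 IP libraries (23.6% ± 0.199, SD, n = 2, against 28.8% ± 1.88 in NTC IP and 22.2% in the NTC input) could come from more background reads in these IPs. Mixing 78.5% of input into the NTC IP would give the L1 share seen, but would also bring satellites to 7.09%, and they stood at 10.7% ± 0.0116, which argues against background as the whole cause. A gradient that also separates the NTC pair stays open: the mean guide change followed NTC 1 minus NTC 2 across subfamilies (r = 0.586), and with that difference regressed out the median L1 change went from -0.27 to -0.153, keeping 55.9% of its size. The NTC libraries enter both sides of this regression, so a deviation of NTC replicate 2 alone would also make r positive. The part of the L1 change that remains therefore cannot tell whether the gradient is the whole cause. Such a gradient may reflect base composition, since L1 is rich in A and T and Alu in G and C, but no repeat sequences were used here to test it. Loss of H3K9me3 from L1 after SETDB1 disruption remains among the open explanations.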
